A study of Oncorhynchus kisutch with 206 samples.

How the data were processed

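Gene expression was measured in the brain of coho salmon (Oncorhynchus kisutch) on 2-colour microarrays, each with 1 fish. Per the labels' protocols, RNA was extracted from the tissue, amplified, and coupled to Alexa 555 for the fish and to Alexa 647 for a reference made by pooling all brain samples. No array had the dyes the other way round, so a dye effect would be shared by every array. The arrays lie on 61 slides, with 1 to 4 of them on a slide. Feature extraction, background treatment, normalization within arrays and the filter that left values empty are not given in the sources used here.

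The deposited values were read as log2 ratios of fish over pool. No label states the log base or the direction, so both rest on the values and are called likely. Among probes with values on at least 200 arrays, taken in 10 classes of variance, log2 of the mean of the back-transformed values stayed between 0.06 and 0.21 when read as fish over pool, as a pool of the same fish would give, and ran from -0.07 to 1.16 when read as pool over fish. Read as log10 values the class medians ran from 1.29 to 2.80, and read as natural log values from 0.20 to 0.38, so a natural log is not excluded; counts of called probes without a fold limit do not depend on the base. Folds, the 1.5-fold limit and the folds of the simulation do; read as natural logs, 4194 of the 7235 probes called in fall against summer would pass 1.5-fold instead of 1630. Among 1431 probes whose share of empty values differed by at least 0.5 between stages, 69.9% had lower ratios in the stages with more empty values, with a median correlation of -0.26 over the 6 stages; for 2677 probes over the 3 largest stages the share was 70.7% and the median correlation -0.62. Array medians lay between -0.11 and 0.19, with a median of 0.01, and the scale of single arrays (SD 0.51 to 1.61) was kept as deposited.

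A second deposited table holds the same values in units that its columns do not name, treated as "other" here; all cells of the 43630 probes were identical in both tables (100%), and it adds 18 control rows. A share of 34.5% of the values was empty, from 16.6% to 57.6% per array. In total 10942 probes had a value on every array. Correlations between pairs of arrays over these probes ran from -0.49 to 0.92 with a median of 0.24, and 1.12% of the 21115 pairs lay below -0.3; the dyes are stated in the labels and the stages can oppose each other, so the direction was kept. No pair of arrays held the same values. The number of arrays limits the precision.

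The groups, tests, terms and most alternatives were fixed before the data were examined. Stage was taken from the season in the labels, and fish number is the replicate, with each number taken as a separate animal. Among fish with a usable mass label, 2 pairs shared the labels of length, mass, sex, origin, place, year and stock. They were smolts 1547 and 1548 (10.4 cm, on different slides) and summer fish 2890 and 2918 (18 cm, on slide 43). Their arrays correlated at 0.39 and 0.63. In each stage 1275 pairs can be formed, of which 375 and 58 had a higher correlation, and each of the 4 fish had other arrays closer to it. The values therefore do not single these pairs out as repeats, and do not exclude it either. Results without 1 fish of each pair were computed. Fish without a usable mass label, which include all spring fish, were left out of this check. Spring fish 2115 and 2131 shared the other labels, and both were kept throughout. The probes carry position names (C for column, R for row) and no gene names, and no table used here pairs them with genes. The gene lists fixed at the same time could therefore not be tested, and probes are given by name: for each comparison, at most the 2 called probes with the largest rise and the 2 with the largest fall.

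The tests were fitted with limma 3.58.1 in R 4.3.3: a linear model per probe, the slide as a random block with 1 consensus correlation (estimated on 2000 probes with values on at least 50% of the arrays, and 0.18 in the fit of the 6 stages), moderated variances, and Benjamini-Hochberg adjustment at 0.05 over the probes with at least 3 values on each side. Empty values were left out probe by probe. The 5 steps between consecutive stages came from 1 fit over all arrays. Hatchery against wild fish was tested in smolts with river as a term and in ocean fish of summer, fall and winter with stage and year as terms. Male against female used stage as a term, 2009 against 2008 used stage and place, and west coast against Strait of Georgia used stage and year. The least-squares code written for the empty values was set against limma's own functions on 500 probes; log2 changes differed by at most 1.94e-15 and log10 p by at most 1.42e-14.

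The test was tried on simulated arrays with the real empty values, slides, probe variances and slide correlation, in which 200 probes per comparison were changed. The probes were drawn independently, while real probes move together over whole arrays. The recovered shares therefore hold for the simulation and may differ in the real tests. In smolt against parr the simulation made 3 false calls, where shuffled groupings of the real fish called up to 505. Of probes changed 1.5-fold, 65.7% were recovered in fall against summer, 16.4% in spring against smolt and 5.97% in smolt against parr; of probes changed 4-fold, 100%, 98.5% and 83.3%. In male against female 77.6% of the probes changed 1.5-fold were recovered, in hatchery against wild ocean fish 59.7%, and in hatchery against wild smolts 10.4%. The steps between stages were simulated on the probes tested in them (38633 in fall against summer, 34929 in spring against smolt, 31780 in smolt against parr), and the other comparisons on all probes with at least 3 values on each side (38665, 37892 and 33865 in the order given).

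Principal components were computed over the 10942 complete probes after centring each probe; scores are array loadings times 100, signed so that fall fish lie high. Differences of mean score and correlations with fork length were tested with 100000 permutations (two-sided). The components, their relation to fork length, the courses over the stages, the persistence of sea-entry changes, the tests of differences between years, coasts or origins by stage, hatchery against wild fish within parts of fall, the steps within slides and the control rows were all chosen after first results were seen. Alternatives were the slide as a fixed term or no slide term, median centring, quantile normalization, a filter on the interquartile range, array weights, a 1.5-fold limit, other terms and parts of the samples; those added after the first results were seen are named in the closing section. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the checks and plots.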

Results

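Coho salmon brains were profiled from freshwater rearing to the first winter at sea. The fish fall into 6 life stages: 5 parr and 51 smolts caught in rivers, and 12 fish of ocean spring, 51 of ocean summer, 78 of ocean fall and 9 of ocean winter. Parr are the river-dwelling juveniles and smolts the fish that migrate to sea. Fork length was 5.06 ± 0.305 cm (SD, n = 5) in parr, 11.2 ± 1.22 cm (n = 51) in smolts, 11.5 ± 1.14 cm (n = 12) in spring, 17.6 ± 2.29 cm (n = 51) in summer, 25.1 ± 3.33 cm (n = 78) in fall and 34.5 ± 2.32 cm (n = 9) in winter. Ratios are to a pool of all brain samples and are likely fish over pool, a direction taken from the values and not from a label; with the other direction, higher and lower would change places in every comparison. The log base is read as 2 and a natural log is not excluded, which would make every fold larger; folds below hold for log2 unless the natural log is named. Each array held 43630 probes, of which 16.6% to 57.6% had no value. The mean share of empty values was 26.4% in parr and 37.4% in fall.

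Brain expression differed among the life stages for 12715 of 39950 tested probes (31.8%; limma F test, adjusted p under 0.05). Of the 12013 called probes with at least 3 values in every stage, 3907 were closest to a steady trend from parr to winter (2117 rising and 1790 falling), and 3433 were closest to a step between summer and fall. A further 1891 had fall apart from the other stages, 1206 had a step between fresh water and the sea, and 629 had a rise or dip shared by spring and summer. The test and the assignment to a course both weigh a stage by its number of fish, so a change of a given size counts more where it parts large groups. Over 12 alternatives the test among the stages called 3961 probes (slide as a fixed term) to 23095 (array weights).

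**Figure D1:**
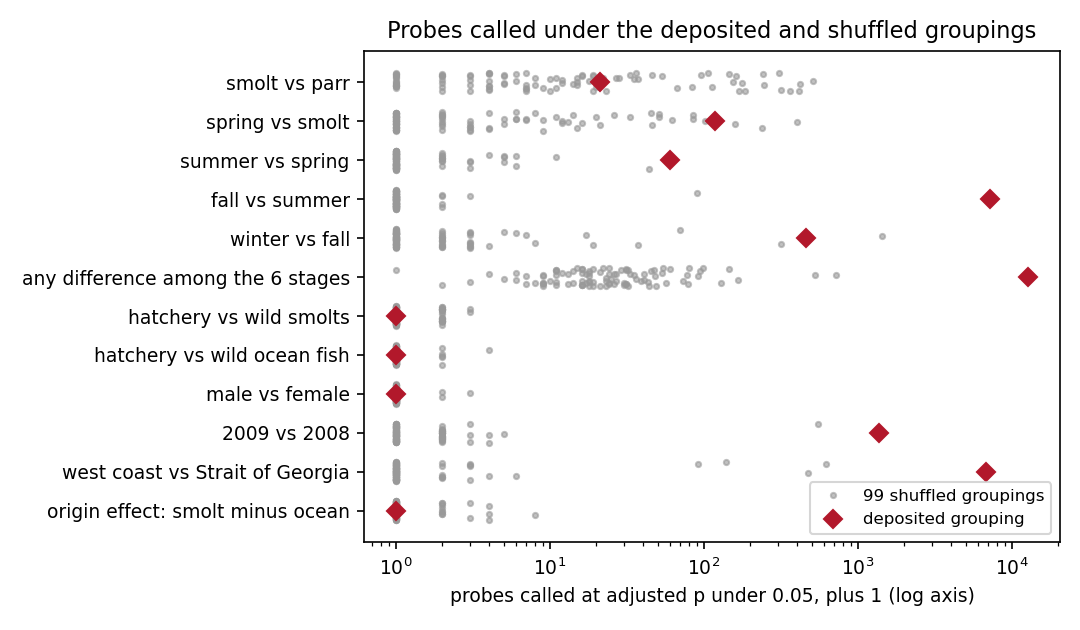
Number of probes called at an adjusted p under 0.05 in each comparison, plus 1 on a log axis; the diamond is the real grouping and the grey points are 99 shuffled groupings of the same samples. Fall against summer reached 7235 probes where the highest shuffled grouping reached 89, while smolt against parr, with 20 probes, lies inside its shuffled groupings.

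A stage order also appeared in the main axes of variation. Component 2, with 7.10% of the variance, rose from -12.7 ± 1.68 (SD, n = 5) in parr to -6.72 ± 3.78 (n = 51) in smolts, -5.71 ± 2.95 (n = 12) in spring, -0.207 ± 4.79 (n = 51) in summer and 5.63 ± 4.65 (n = 78) in fall, and stood at 5.14 ± 4.28 (n = 9) in winter. The summer mean joins unlike years. The 8 summer fish of 2008, all from the Strait of Georgia, averaged -6.11 ± 1.83, close to spring. The 35 Strait summer fish of 2009 averaged 1.44 ± 3.93. The smolt mean does so too. All 5 parr were hatchery fish of the Chilliwack river in 2008, while 35 of the 51 smolts came from other rivers in 2009. On average the 16 smolts of the parr's river and year lay nearer to the parr than those of 2009. The step from parr to smolt on this axis was not tested within that river and year. The steps from parr to smolt (permutation test, adjusted p = 0.0033), spring to summer (0.00247) and summer to fall (2.0e-04) passed the test over 20 steps; smolt to spring (0.773) and fall to winter (0.91) did not. Stage accounted for 62.2% of the variance of component 2 and slide for 62.9%, where shuffled labels took 2.42% and 29.2% on average, since the slides are many. Within slides that held both stages, summer to fall moved by 7.42 (23 and 21 fish on 15 slides; permutation p = 4e-05, adjusted 3.2e-04) and spring to summer by 4.74 (permutation p = 0.0231, adjusted 0.0616); parr and smolts shared 2 slides, too few for a value. Component 1, with 32.6% of the variance, was shared with the slide (57.8%, against 29.4% on average with slide labels shuffled). It was also shared with the SD of the array (47.5%) and its share of empty values (24.0%), and less with the stage (7.55%, against 2.46% shuffled). From summer to fall component 1 rose by 3.35 (permutation test, adjusted p = 0.0308 over 20 steps), and its other steps did not pass.

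**Figure D2:**
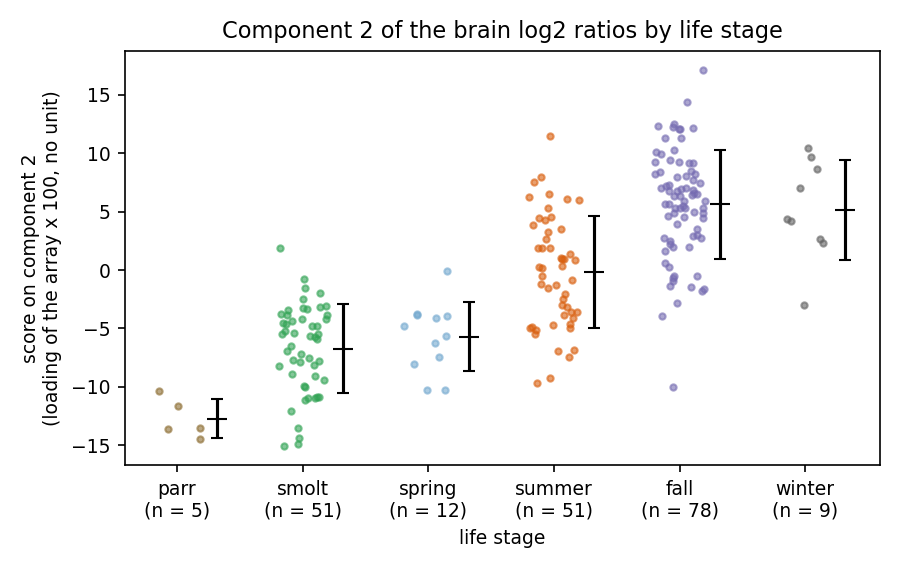
Score of each fish on component 2 of the log2 ratios (array loading times 100, no unit) by life stage, with mean and SD. Scores climb from -12.7 in parr to 5.63 in fall.

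Within the growing ocean stages, larger fish lay further along this axis. In summer, component 2 correlated with fork length (Pearson r = 0.567, permutation p = 1e-05, adjusted 6.0e-05; Spearman rho = 0.552, permutation p = 2e-05, adjusted 2.4e-04; n = 51), and in fall as well (Pearson r = 0.492, permutation p = 1e-05, adjusted 6.0e-05; Spearman rho = 0.472, permutation p = 4e-05, adjusted 2.4e-04; n = 78). The Pearson p of 1e-05 is the smallest that the permutations can give, and 12 relations were tested. Without the 2 fish farthest from the median length, r was 0.505 in summer and 0.458 in fall. Within places and years with at least 6 fish it was 0.505, 0.769 and 0.792 in summer (29, 8 and 6 fish) and 0.440, 0.499, 0.601, 0.204 and 0.620 in fall (11, 21, 17, 7 and 22 fish). Within slides that held more than 1 fish of the stage it was 0.446 in summer (34 fish on 15 slides) and 0.202 in fall (66 fish on 24 slides). In smolts, which spanned 8.4 to 13.4 cm, no relation was found (Pearson r = 0.0630, permutation p = 0.662, adjusted 0.854; Spearman rho = 0.00535, permutation p = 0.971, adjusted 0.971; n = 51; r = 0.0795 without the 2 farthest fish). Within the 5 rivers, the smolt values ran from -0.413 to 0.236.

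**Figure D3:**
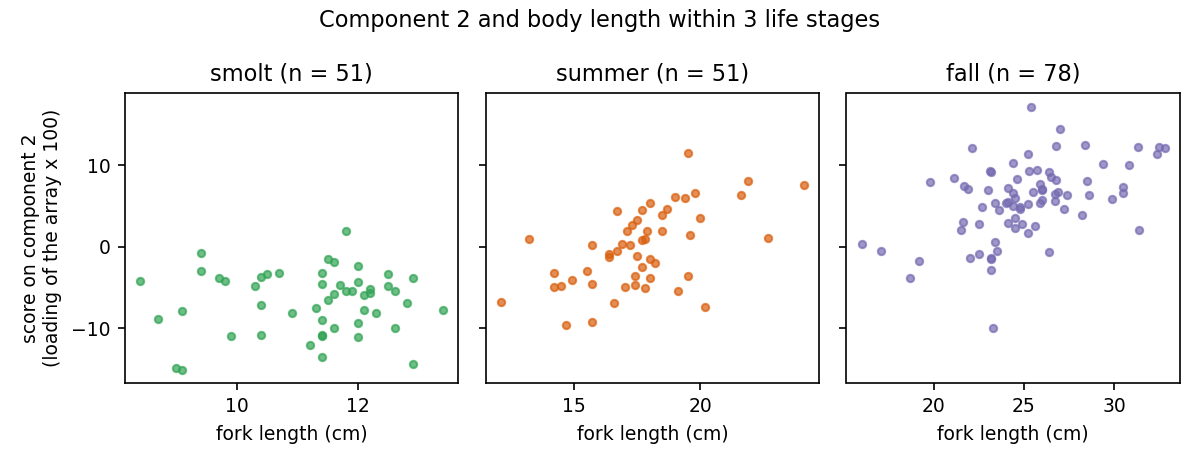
Score on component 2 (array loading times 100) against fork length in cm for each fish of 3 stages. The score rises with length in summer (r = 0.567) and fall (r = 0.492) and not in smolts (r = 0.0630).

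From parr to smolt, the preparation for life at sea, 20 probes passed the test, 14 higher and 6 lower in smolts among 31780 tested, in a comparison with 5 parr in which 31.3% of simulated changes of 2-fold were recovered. Probe C138R021 rose 8.00-fold, or 20.1-fold on a natural log (log2 change 3.00, SE 0.45, adjusted p = 6.9e-06 by limma), from -3.22 ± 1.21 (SD, n = 5) in parr to -0.29 ± 1.05 (n = 51) in smolts, and later means lay between -0.38 in spring and 0.72 in winter. C031R127 rose 5.73-fold (log2 change 2.52). C104R073 (log2 change -2.24, 4 parr and 20 smolts with a value) and C175R128 (-2.17, 3 parr and 10 smolts) were lower in smolts. With slide as a fixed term these last 3 probes lost their call (adjusted p = 0.185, 0.502 and 0.574). The change of C031R127 stayed near its size, at 2.34 (SE 0.66, against 0.46 before), while those of C104R073 and C175R128 were smaller, at -1.50 (SE 0.61, against 0.43) and -1.41 (SE 0.61, against 0.32). Of the 12 probes called in that fit 2 were among the 20; 3 of the 5 parr shared a slide. The count did not stand apart from shuffled groupings of the same fish, and it was 9 without parr 38, 7 without parr 39, 32 after quantile normalization (56.3% of them higher, against 70%), 83 without a slide term and 1047 with array weights. Against hatchery smolts of the parr's own river and year 14 probes were called, 5 of them among the 20, and C138R021 missed the threshold (log2 change 2.37, SE 0.55, adjusted p = 0.0532).

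At entry into the sea, from river smolts to ocean spring, 116 of 34929 tested probes were called, 88 lower and 28 higher in spring with the ratios read as fish over pool, and 88 higher and 28 lower with the ratios turned. C217R043 fell by 2.21 on the log2 scale (SE 0.25, adjusted p = 2.6e-11 by limma), from 1.44 ± 0.91 (SD, n = 51) in smolts to -0.88 ± 0.73 (n = 12) in spring; all 12 spring fish lay below the smolt mean, and the later ocean stages had means between -1.01 and -0.77. C009R155 rose 4.43-fold (log2 change 2.15, SE 0.33, adjusted p = 3.9e-06), from -1.84 ± 1.12 (n = 51) to 0.14 ± 1.46 (n = 12), and stood at -0.99 ± 0.57 (n = 9) in winter. C044R036 rose by 1.69 on the log2 scale in spring, with later means of 0.58 in summer and -0.55 in winter. The fitted change of C172R057 (-1.85) rests on 1 of 3 spring fish: fish 2125 had -4.83 and the others -0.17 and -0.20, against a smolt mean of 0.13. The spring fish were wild and caught in 2009; 38 probes were called in fish of 2009, 27 in wild fish, 63 with origin as a term, 27 with slide as a fixed term, 244 after quantile normalization (36.1% of them higher, against 24.1%) and 1466 with array weights.

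From spring to summer 59 of 35076 tested probes were called, 53 of them higher in summer with the ratios read as fish over pool, and 53 lower with the ratios turned. C124R072 rose 7.88-fold, or 19.6-fold on a natural log (log2 change 2.98, SE 0.50, adjusted p = 0.000198 by limma), from -3.34 ± 1.36 (SD, n = 12) to -0.45 ± 1.87 (n = 51), and C210R135 rose 6.70-fold with a like course over the stages. C028R013 fell by 1.74 on the log2 scale and C250R011 by 1.21, with winter means of -0.02 and 0.48. Of the called probes, 3 remained with slide as a fixed term; C250R011 was not among them (adjusted p = 0.0811), though its change was no smaller there, at -1.28 (SE 0.29) against -1.21 (SE 0.24). After quantile normalization 214 were called, in fish of the south Strait of Georgia 466 and with array weights 1355.

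**Figure D4:**
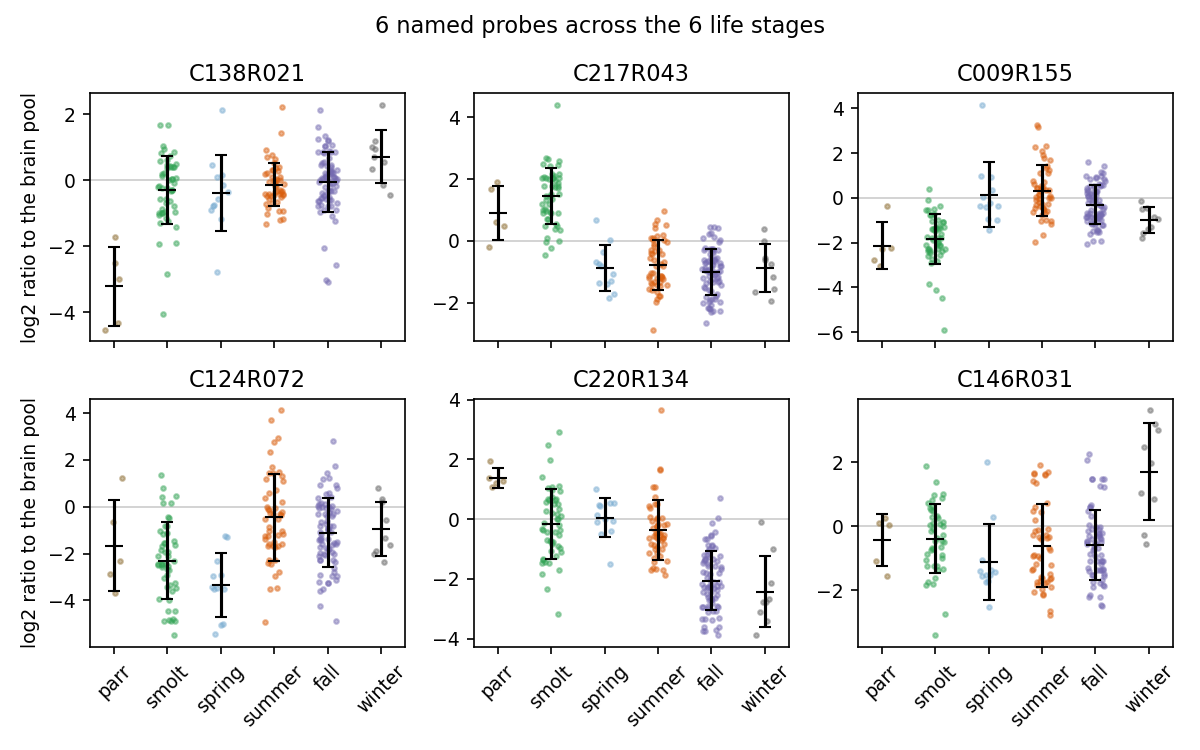
Log2 ratio to the brain pool of each fish with mean and SD for 6 named probes by life stage. C217R043 drops between smolt (1.44) and spring (-0.88), C220R134 between summer (-0.36) and fall (-2.06), and C138R021 is low in parr (-3.22).

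The step from ocean summer to ocean fall, which compares the 2 largest of the ocean groups, called the most probes of the 5 steps. Of 38633 tested probes, 7235 (18.7%) were called, 3610 higher and 3625 lower in fall. By at least 1.5-fold 644 were higher and 986 lower, and on a natural log 1920 and 2274, so whether most changes were under 1.5-fold depends on the log base. C043R150 fell by 1.64 on the log2 scale (SE 0.18, adjusted p = 1.4e-12 by limma), from -0.34 ± 0.85 (SD, n = 51) to -1.94 ± 0.91 (n = 78), and C220R134 fell by 1.74 (SE 0.20, adjusted p = 6.5e-12); 75 of 78 fall fish lay below the summer mean for each of these probes. Both probes were highest in parr (1.06 and 1.37) and stayed low in winter (-2.08 and -2.43). The largest rises, C138R027 and C102R130, had values on 5 and 7 fall fish and rest mainly on fish 358 (3.88 and 2.85) and fish 766 (4.44 and 4.01); with year as a term both lost their call (adjusted p = 0.168 and 0.413), at 1.96 (SE 0.98) against 2.35 (SE 0.71) and at 1.46 (SE 1.19) against 2.03 (SE 0.68). With slide as a fixed term 1827 of the 7235 probes were still called. The 17 control rows tested in this step were all higher in fall (median log2 change 0.21, against 0.03 over all tested probes), none past the threshold after adjustment. In fish of 2009, 14206 probes were called, with 6410 shared; in fish of 2008, with 8 summer fish, 4434 were called, with 1054 shared; wild fish gave 1355.

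Winter brains differed from fall brains in 461 of 31534 tested probes, 198 higher and 263 lower. C146R031 rose 4.94-fold (log2 change 2.31, SE 0.40, adjusted p = 0.000269 by limma), from -0.60 ± 1.10 (SD, n = 68) to 1.70 ± 1.52 (n = 9), a level no other stage reached on average. The fitted rise of C069R003 (2.79) rests mainly on 1 of 3 winter fish: fish 4217 had 6.03 and the others 0.44 and 1.14. C019R088 fell by 1.82 on the log2 scale, from -1.25 ± 1.52 (n = 78) to -3.19 ± 0.55 (n = 9), and C145R138 by 1.60; with place as a term both lost their call (adjusted p = 0.138 and 0.159), at -1.34 (SE 0.41, against 0.42 before) and -1.19 (SE 0.38, against 0.45). Both also missed the threshold with slide as a fixed term (-1.58, SE 0.43, adjusted p = 0.0602, and -1.23, SE 0.46, adjusted p = 0.275) and after quantile normalization (-1.67, SE 0.45, adjusted p = 0.0557, and -1.56, SE 0.42, adjusted p = 0.0518). Of the 9 winter fish 6 came from the west coast of Vancouver Island, against 24 of 78 in fall; 9 probes were called within the west coast, 120 with place as a term and 3284 in fish of 2009. Of the 461, 112 were among the 131 called with slide as a fixed term. After quantile normalization 150 were called, 18.7% of them higher, against 198 of 461 before; with year as a term 1629 were called, and with array weights 9091.

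On the fourth axis of variation winter fish lay low, and so did summer and fall fish of the west coast and of 2008. Slide accounted for 60.1% of the variance of component 4 (29.2% on average with slide labels shuffled) and stage for 12.97% (2.42% shuffled). It averaged -7.92 ± 5.49 (SD, n = 24) in west coast fall fish and 4.07 ± 5.46 (n = 54) in fall fish of the Strait of Georgia, the inland sea between Vancouver Island and the mainland. By year, west coast fall fish averaged -9.52 in 2008 (n = 17) and -4.03 in 2009 (n = 7), and Strait fall fish -1.86 in 2008 (n = 11) and 5.59 in 2009 (n = 43). Summer fish of the Strait averaged -7.03 ± 6.58 in 2008 (n = 8) and 3.31 ± 5.37 in 2009 (n = 35). West coast summer fish, all of 2009, averaged -2.59 ± 3.98 (n = 8). Winter fish, all of 2009, stood at -10.1 ± 2.72 (n = 6) on the west coast and at -14.8 ± 2.62 (n = 3) in the Strait. Winter differed from fall on this axis over all fish (difference -12.1, permutation p = 2e-05, adjusted 2.0e-04), and on the west coast alone the difference was -2.17 (permutation p = 0.361, adjusted 0.672 over 4 components). On the 8 slides that held both stages (9 winter and 22 fall fish) the difference within slides was -7.11 (permutation p = 0.00353, adjusted 0.0141 over 8 tests).

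Fish of the west coast and of the Strait of Georgia differed widely in the same seasons. Of 37387 tested probes, 6750 were called, 4380 lower and 2370 higher on the west coast, with 1286 lower and 550 higher by at least 1.5-fold (3032 and 1534 on a natural log). Of the 6750, 2054 were still called with slide as a fixed term, and 1000 when the fish were limited to stock regions caught on both coasts with stock region as a term (10 west coast and 56 Strait fish). In fall of 2009 2873 probes were called, in fall of 2008 663, and in summer 13 (8 west coast and 43 Strait fish). A wide difference was thus seen in fall and not shown in summer. The probes with the largest fitted differences, C121R056, C058R023, C132R155 and C261R062, each had values on 3 west coast fish and are given without a mean.

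Fish of 2009 and 2008 differed in 1371 of 36526 probes in ocean summer and fall, 776 higher and 595 lower in 2009. That fit takes the year difference as equal in summer and fall. A test of whether it differed between these stages called 5238 of 29237 probes (limma, interaction term), as weighed further below. The 1371 are therefore not shown to differ alike in both seasons. At 1.5-fold or more there were 476, and 1070 on a natural log. The largest fitted differences, at C102R015, C224R007, C059R160 and C196R076, rest on 3 to 6 fish of 2008 each. Slide as a fixed term left 84 called probes, 56 of them among the 1371; without a slide term 2112 were called, and with array weights 4943.

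No single probe passed the test between hatchery and wild fish. Among smolts 0 of 33709 probes were called by limma (2748 at an unadjusted p under 0.05), and among ocean fish 0 of 37856 (4596 unadjusted). For a hatchery effect that differed between smolts and ocean fish, 0 of 33660 probes were called (3943 unadjusted). That last fit had stage and not river as a term, so its smolt part mixes origin with river. Its power was not simulated, so a difference is not excluded. In fall alone 2007 probes were called, 1236 with place as a term, and without the 17 west coast fish of 2008 limma called 0 (4010 unadjusted). With array weights 2361 probes were called in smolts. With river as a term the smolt comparison rests on the rivers that held both origins. These were Chilliwack (10 hatchery and 6 wild fish) and Capilano (7 and 3). In its simulation 10.4% of the probes changed 1.5-fold and 41.8% of those changed 2-fold were recovered.

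Between males and females 0 of 38585 probes were called by limma (1033 at an unadjusted p under 0.05). With array weights 1 probe was called.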

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

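The tests of year by stage and coast by year, and of array quality, place with year and stock as explanations of the changes from summer to fall and between the coasts, were chosen only after the result was seen, as was the bound for slide in those changes, whose fit was planned; the regroupings of samples, the slide and single-fish tests of year by stage and the length test were set before theirs.

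The change from summer to fall differed between 2008 and 2009 in 5238 of 29237 probes (limma, interaction term), and in 9768 of 28454 when fish of the Strait of Georgia alone were compared, where all 8 summer fish of 2008 were caught. Chance can be excluded: 1 of 100 splits, the real one, gave as many, and the highest other split gave 510. No single summer fish of 2008 accounted for the count, which stayed at or above 2325 without any 1 of the 8 fish; it was 2325 without fish 552, 2507 without fish 516, 3409 without fish 502 and 7995 without fish 579. With slide as a fixed term 130 of the 5238 probes (2.48%) were still called, so slide differences stay open as a candidate explanation, though that fit also has less power. Array quality stays open too. Fish 516, 552 and 576 are among the 9 widest arrays of the study (SD 1.41, 1.29 and 1.30). Component 1 averaged 6.95 ± 10.8 (SD, n = 8) in summer fish of 2008, against -1.97 ± 4.43 (n = 35) in Strait summer fish of 2009. The test of year by stage was not run without these arrays or with array quality terms. A difference between the years in the fish themselves stays open and untested.

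The 7235 probes that separated fall from summer were not a matter of chance, since 1 of 100 splits, the real one, gave as many and the highest other gave 89. Slide as a fixed term kept 25.3% of the calls, array spread and empty values as terms kept 54.3%, and place and year as terms kept 90.4%. None of these, as entered, accounts for the whole set. Whether they account for the calls that ended stays open, since the fit with slide as a fixed term also has less power. The year term takes the change as equal in both years, while the test of year by stage called 5238 probes as unlike. Slide differences and array quality stay open for those calls, and their overlap with the 7235 was not computed. Besides, 43 of the 51 summer fish were of 2009. The fit with place and year as terms therefore cannot show that the set does not depend on year. Fewer of the 7235 probes were also called in fish of 2008 than in fish of 2009, with the counts given above. A part of the 7235 even had the opposite direction in fish of 2008. The share that kept its direction there is given in the closing section. Growth is a hypothesis on the biological side: within stage, place and year, 82.8% of the called probes had a slope on fork length with the sign of the stage change, and 3 of 100 assignments of length, the real one included, gave as large a share. The highest of the shuffled ones gave 85.1%, so the margin is narrow, and 289 of 27975 probes had a slope called on their own. Season and age vary with stage and were not tested.

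The 6750 probes that separated the west coast from the Strait of Georgia exceeded chance, with 1 of 100 splits, the real one, giving as many and 622 in the highest other. With slide as a fixed term 30.4% of them were still called, so slide differences do not account for the whole set. Among stock regions caught on both coasts, 14.8% were still called with stock as a term; that comparison has 10 west coast fish, so the calls that ended may reflect fewer fish as well as stock. Length differed between the coasts as well: in fall of 2009 the west coast fish were longer on average than the Strait fish. No coast fit had length as a term, so a part of length in these calls was not tested. Place of capture stays open as a biological difference.

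The coast difference changed between the years in fall for 19 of 28478 probes (limma, interaction term). One winter fish had 50.1% of its values empty, against 35.0% in the next highest of the 9. Among the parr, 1 fish had a log2 ratio of 0.32 at C019R088, and the next highest of the 5 had -1.70. These are 2 far samples among 47 groups looked at, where chance gives about 1 in 20.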

How the results depend on the processing

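The spatial trend, array quality terms, removal of 1 fish of each pair with the same labels and a usable mass, removal of the widest arrays, the filter to probes with values on most arrays, place or place and year as terms, shared stock regions, and the coast tests in summer, fall of 2008 or fall of 2009 were tests chosen only after the result was seen. Of 207 counts under an alternative, 142 stayed within 1.5 times of the count first given and 65 did not; of 480 values of named probes, 431 kept direction and call, 48 kept direction and lost the call, and 1 turned, C121R056 between the coasts, at -0.0163 with array quality terms. Except under a 1.5-fold limit, which can only take calls away, the cause was not tested. Fewer fish is no settled cause either, since some counts rose in parts of the samples, as given below.

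Without a slide term 83 probes were called in smolt against parr, 5 in hatchery against wild smolts and 2112 in 2009 against 2008. With slide as a fixed term the counts were 12 in smolt against parr, 27 in spring against smolt, 3 in summer against spring, 1956 in fall against summer, 131 in winter against fall, 3961 among the 6 stages, 84 between years and 2170 between coasts. Quantile normalization gave 32, 244, 214 and 150 in smolt against parr, spring against smolt, summer against spring and winter against fall. Array weights gave 1047, 1466, 1355, 13318 and 9091 in the 5 steps in order, 23095 among the 6 stages, 2361 in hatchery against wild smolts, 1 in male against female, 4943 between years and 3 in the origin effect of smolts minus ocean fish. The 1.5-fold limit left 1630 in fall against summer, 476 between years and 1836 between coasts. Without the spatial trend 38 were called in smolt against parr, 1 in hatchery against wild smolts and 4 in the origin effect. Array quality terms gave 38 in smolt against parr, 39 in summer against spring, 4562 in fall against summer, 1 in hatchery against wild smolts and 2293 between years. Without the widest arrays (9 arrays with an SD above 1.19) there were 49 in smolt against parr, 279 in winter against fall, 2 in hatchery against wild smolts and 1 in hatchery against wild ocean fish.

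Origin as a term gave 63 in spring against smolt and 26 in summer against spring, year 1629 in winter against fall, array position 98 in summer against spring, and place 120 in winter against fall. With only the compared stages, 8 were called in smolt against parr and 42 in spring against smolt. Leaving out 1 parr at a time gave 7 to 26 probes, with 9 without parr 38 and 7 without parr 39. In 2009 fish 38 were called in spring against smolt, 14206 in fall against summer and 3284 in winter against fall; in 2008 fish 4434 in fall against summer, where 62.9% of the 7235 probes kept their direction. Wild fish gave 27 in spring against smolt, 31 in summer against spring and 1355 in fall against summer. Fish of the south Strait gave 466 in summer against spring, those of the west coast 9 in winter against fall, Chilliwack smolts 1 in hatchery against wild, and fall fish 2007 in hatchery against wild ocean fish. Between coasts, fall gave 2761, shared stocks 1084, summer 13, fall of 2008 663 and fall of 2009 2873.

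Median centring, the interquartile range filter, the second table, the removal of fish 1548 and 2918 and the filter to probes with values on most arrays moved no count by over 1.5 times. The 1.5-fold limit on the test among the 6 stages and both gene list alternatives were not run. No paired analysis was possible because the groups share no replicate numbers. Signal over background was not analysed here.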

Other observations

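The tests of sea-entry persistence, of origin within parts of fall and of control rows and the adjustment over the regroupings were chosen only after the result was seen; the regroupings of samples were planned.

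Whether changes at sea entry were carried through to fall stays open. Probes were selected by comparing spring fish with 25 of the smolts, which called 283 (55 higher and 228 lower), more than the 116 called with all 51 smolts, and were then measured against the other 26. In summer 222 of the 283 (78.4%) lay on the same side of these smolts as in the selection, with median log2 differences of 0.27 for the rises and -0.18 for the falls. In fall 151 of 283 (53.4%) did, with medians of 0.05 and -0.02, and in winter 154 of 282 (54.6%). Against parr, fall lay on that side in 177 of 282 (62.8%), with medians of 0.16 and -0.16. The share in spring, 282 of 283, rests on the spring fish of the selection, so part of the loss by fall may come from that selection. With 6 of the 12 spring fish held out as well, 22 probes were called, 4 higher and 18 lower. The held-out spring fish lay on the same side in 20 of the 22, with medians of 0.90 for the 4 rises and -0.48 for the 18 falls, and fall fish in 16 of 22, with medians of 0.31 and -0.49. Probes move together, so these shares have no test attached.

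In fall of 2008 on the west coast, 5 hatchery and 12 wild fish differed in 3726 of 27236 probes by limma, 2369 of them lower in hatchery fish. With slide as a fixed term 80 were called. In the 3 other parts of fall that were tested limma called 0 probes between hatchery and wild fish: in the south of the Strait in 2009 (1756 unadjusted) and in the rest of the Strait in 2008 (2102 unadjusted) and 2009 (1997 unadjusted). The west coast in fall of 2009, with 1 hatchery and 6 wild fish, was not tested. All 5 hatchery fish came from stock regions of Columbia, Puget Sound or Washington, against 5 of the 12 wild fish, so origin and stock overlap there. Length differed too: the hatchery fish measured 22.5 to 23.5 cm and the wild fish 16.0 to 32.8 cm. The spread of the arrays differed as well, with an SD of 0.85 to 1.18 in the hatchery fish and 0.67 to 0.99 in the wild fish. Array quality was not tested as an explanation in this part. A difference of the hatchery effect between summer and fall was called by limma in 0 of 32830 probes (3545 unadjusted).

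Regroupings of the same fish set the other counts against chance. Here and above, stages were shuffled freely over slides, places and years, and the other groupings freely over slides. Chance therefore means a random assignment of fish that ignores these. Chance in that sense can be excluded, also after adjustment over 13 comparisons, for summer against spring (59 probes, 1 of 100 splits gave as many, highest other 43). The same holds for the 6 stages (12715, 1 of 100, highest other 719) and 2009 against 2008 (1371, 1 of 100, highest other 546). Winter against fall (461, 2 of 100) passed the same bound, though 1 split other than the real one called 1423 probes. For spring against smolt (116 probes) 4 of 100 gave as many and the highest other gave 403. This share lies under 0.05 alone and at 0.065 after that adjustment, so whether chance is excluded depends on the adjustment. Chance cannot be excluded for smolt against parr (20 probes, 30 of 100, highest other 505). With 0 probes, all 100 of 100 splits gave as many in hatchery against wild smolts (highest other 2), hatchery against wild ocean fish (highest other 3), male against female (highest other 2) and the origin effect of smolts minus ocean fish (highest other 7). A count of 0 fixes that result in advance, so it carries no information. These comparisons are still counted among the 13 of the adjustment, which raises the adjusted share of the others. Some splits called several times the real count, as in smolt against parr, spring against smolt and winter against fall. The cause of these high counts was not tested.

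Of 68 tests of control rows over the 5 steps limma called 0, and 10 had an unadjusted p under 0.05. All 10 were in fall against summer and higher in fall, by 0.13 to 0.78 on the log2 scale (lowest adjusted p = 0.0652), and all 17 rows tested in that step were higher in fall. Rows on the same arrays move together, so the share has no test attached.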
